A study of Mus musculus with 48 samples.

How the data were processed

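Total RNA from the cortex and the hippocampus of 12-month-old mice had been labelled with Cy3 and hybridised to single-colour Agilent mouse arrays, 48 in all, with 8 arrays on each of 6 slides. The mice were APP/PS1 transgenics, called AD in the labels, and their wild-type littermates (WT). APP/PS1 mice carry mutant human transgenes and deposit amyloid plaques. Nicotinamide riboside (NR), a form of vitamin B3 that cells turn into NAD, was given at 12 mM in the drinking water for 5 months, up to the age of 12 months. The protocol in the labels describes NR for APP/PS1 mice, and the group labels also name WT mice given NR (WT_NR). Each region had 6 WT, 6 WT_NR, 7 AD and 5 AD_NR arrays. The labels number the replicates of each group and do not say that an array of the cortex and an array of the hippocampus with the same number came from the same mouse.

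Per the file headers, the scanner files hold fluorescence intensity per spot, written by Feature Extraction 12.0.3.1, which had subtracted the background and removed the spatial trend of each array. These values were not normalised between arrays. The table of values made by the authors holds a score per spot and array. Its column median was -0.24 in all 48 columns, its ranks followed those of the intensities (Spearman correlation at least 0.99999) and its Pearson correlation with the log2 intensities was at least 0.9813. Direction and centring are thus known, as higher scores go with higher signal and each column is centred and scaled to its own spread, while the size of a log2 change cannot be read from it. How the authors made that table is not given in the sources used here, so it served only as an alternative.

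Each array held 62976 spots, of which 59305 were not controls, for 56605 probes. Spots that the extraction software had set aside as uneven were treated as missing, no spot was saturated, and repeated spots of a probe were averaged. The files give accessions and no gene names, so names came from the RefSeq list of assembly GRCm38.p6, used for names only. Matched by accession, 32994 probes matched 1 symbol (22911 symbols) and 23611 matched none. A gene was its symbol, or its accession where no symbol matched. Unmatched genes were tested and counted but are not named here. Among them were the list members Clec7a, Mx1, Mx2, Nnt, Cox5b, Nptxr, Hbb-bs, Trac, Rorb and Oas1b. Nlrp3, Il10 and Steap4 were not well above background on 5 arrays of either region and were not tested.

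The values analysed were log2 intensities minus the 75th percentile of each array. A gene was tested through its probe with the highest mean among probes well above background on at least 5 of the 24 arrays of the region. This left 36825 genes in the cortex, 19721 of them named, and 38149 in the hippocampus, 20261 of them named. In each region 1 linear model with the 4 group means was fitted to all 24 arrays with limma 3.58.1, and the contrasts were AD minus WT, AD_NR minus AD, WT_NR minus WT, and the interaction, the NR difference in AD mice minus that in WT mice. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested, a threshold of 0.05 on the adjusted p and no threshold on the fold. Values after ± are standard errors of a difference or, where a group mean is given, standard deviations. In the fits of 4 groups the standard errors use the spread within all 4, WT_NR included. The difference between regions was tested with both regions in 1 limma model over 36357 shared genes.

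Before the data were examined, 35 gene lists were written, 34 of which were tested in each region as sets and 1 of which held the transgene check. They covered the states of microglia, complement, antigen presentation, interferon-stimulated genes, the cGAS-STING pathway, senescence and its secreted factors, cytokines, NAD metabolism, mitochondria, DNA repair, stress responses, synapse and activity genes, the cell types of the brain, neighbouring brain regions, the circadian clock and sex-linked genes. Sets were tested with camera from limma with a preset correlation of 0.01 between genes, adjusted over the 34 lists. camera compares a list with all other genes, so its direction is relative to them. An estimated correlation per list and fry were alternatives. A score per array was the mean of a list's centred log2 values, compared between AD_NR and AD by a two-sided exact permutation test. The difference made by NR in the genes changed in AD was computed with the AD arrays divided, so that the arrays that chose the genes were not those that NR mice were compared with.

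The genes named were fixed by rule: App and Prnp, with the transgenes in mind; in each comparison the 8 largest rises and the 8 largest falls among genes past the threshold; up to 4 members with the smallest p of each list that passed or held a passing gene; the 4 smallest p in the cGAS-STING, senescence, cytokine, interferon, plaque-associated microglia and NAD lists; always Cgas, Sting1, Cdkn2a, Cdkn1a, Tnf, Il1b, Il6 and Nlrp3; the 3 smallest p in each direction where nothing passed; and the AD genes followed under NR. Marker genes shown for single arrays (Neurod6, Tcf7l2, Tnnt1 and Ttr) were chosen after their values were seen. Some genes that the rule selects are not reported here.

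Tested on simulated data with the real layout, the limma fit found 90.9% of cortex and 92.4% of hippocampus genes given an AD change of log2 2, 50.7% and 58.2% at log2 1, and 8.96% and 25.4% at log2 0.5. For NR in AD mice it found 78.8% and 90.9% at log2 2, 47.8% and 65.7% at log2 1, and 8.96% and 26.9% at log2 0.5. For the interaction it found 74.2% and 69.7% at log2 2, 17.9% and 35.8% at log2 1, and 0% and 2.99% at log2 0.5. Of the lists, complement was shifted by 0.5 in each of the 8 comparisons and found each time. The simulated genes varied independently of each other, with no slide differences and no noisy arrays. These rates and the list result thus do not show how the tests perform on the real, correlated genes. The number of arrays limits the precision. No slide held untreated WT and AD arrays together, so slide was modelled as a fixed block, as a random block and with the array column. Other alternatives were normexp background correction with an offset of 50 followed by quantile normalisation (on the median pixel signal, as the files analysed here have no mean pixel signal), quantile normalisation alone, z-scores per array, the authors' table, no filter, a filter on all arrays, all probes, a replicate block, a sex-linked covariate, array weights and leaving out each array in turn. After seeing the data, arrays in doubt were left out as well: those whose repeated spots had a coefficient of variation over 20% (cortex WT_NR 1 and 2, hippocampus WT_NR 1), 1 with a negative-control standard deviation over 20 (hippocampus AD 1), and those whose genes went against their labels (the mouse labelled WT_NR replicate 6, hippocampus AD_NR 2). The software was R 4.3.3 with the package data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.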

Results

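Gene expression was measured in 2 brain regions of 12-month-old mice to ask what APP/PS1 transgenes change in the cortex and the hippocampus and whether 5 months of NR alter these changes. Each region had 24 arrays, from 6 WT, 6 WT_NR, 7 AD and 5 AD_NR mice. The 75th percentile of the signal lay between 1254 and 4036 intensity units over the 48 arrays. Slide 1 of the cortex held all 6 WT arrays with 2 of WT_NR, slide 2 held 4 WT_NR and 4 AD arrays, and slide 3 held 3 AD arrays with all 5 of AD_NR. The hippocampus lay on slides 4, 5 and 6 in the same order. Untreated WT and AD arrays therefore never shared a slide, and values within the shared slides are given beside the results. Within slides 1 to 6 the median difference over all genes was 0.42, 0.04, 0.13, 0.24, -0.04 and 0.07.

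Prnp, the prion protein gene whose promoter drives the transgenes of this line, separated untreated WT from AD mice in both regions. In the cortex its log2 level was 5.55 ± 0.05 in WT (SD, n = 6) and 6.72 ± 0.10 in AD (SD, n = 7), and in the hippocampus it ran from 5.46 to 5.82 in WT and from 6.29 to 6.80 in AD. The mouse labelled WT_NR replicate 6 had 6.73 in the cortex and 6.54 in the hippocampus, within the AD range in both, though the labels do not state that the 2 arrays come from 1 mouse. The noisy cortex arrays WT_NR 1 and 2 had 6.45 and 6.39, between the ranges of the genotypes and nearer the AD mean. Arrays with noisy spots were set aside when arrays against their labels were sought. The cortex array of the mouse labelled WT_NR replicate 6 also had the AD levels of Cst7 (2.17), an inhibitor of lysosomal proteases in activated microglia, of Itgax (0.34), an integrin of the same cells, and of Gfap (3.71), the filament protein of astrocytes. Of the 393 genes higher in AD cortex, 385 lay nearer their AD mean than their WT mean on that array. In the hippocampus AD_NR replicate 2 stood apart: Prnp was 6.51, within the AD range, but Cst7 was -2.98 against 0.96 to 1.57 on the other AD_NR arrays, and Neurod6, a transcription factor of excitatory neurons chosen after its values were seen, was -3.43 against 1.58 to 2.74 on the other 23. Both were kept under their labels, and counts are also given without them. App itself, whose mouse probe need not read the human transgene, differed by 0.02 ± 0.29 in the cortex (adjusted p = 0.977) and by 0.11 ± 0.16 in the hippocampus (adjusted p = 0.818). App was 7.64, 7.96 and 6.75 on cortex WT_NR 1, 2 and 3, against 5.48 to 5.95 on the other cortex arrays, and the cause was not tested.

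**Figure D1:**
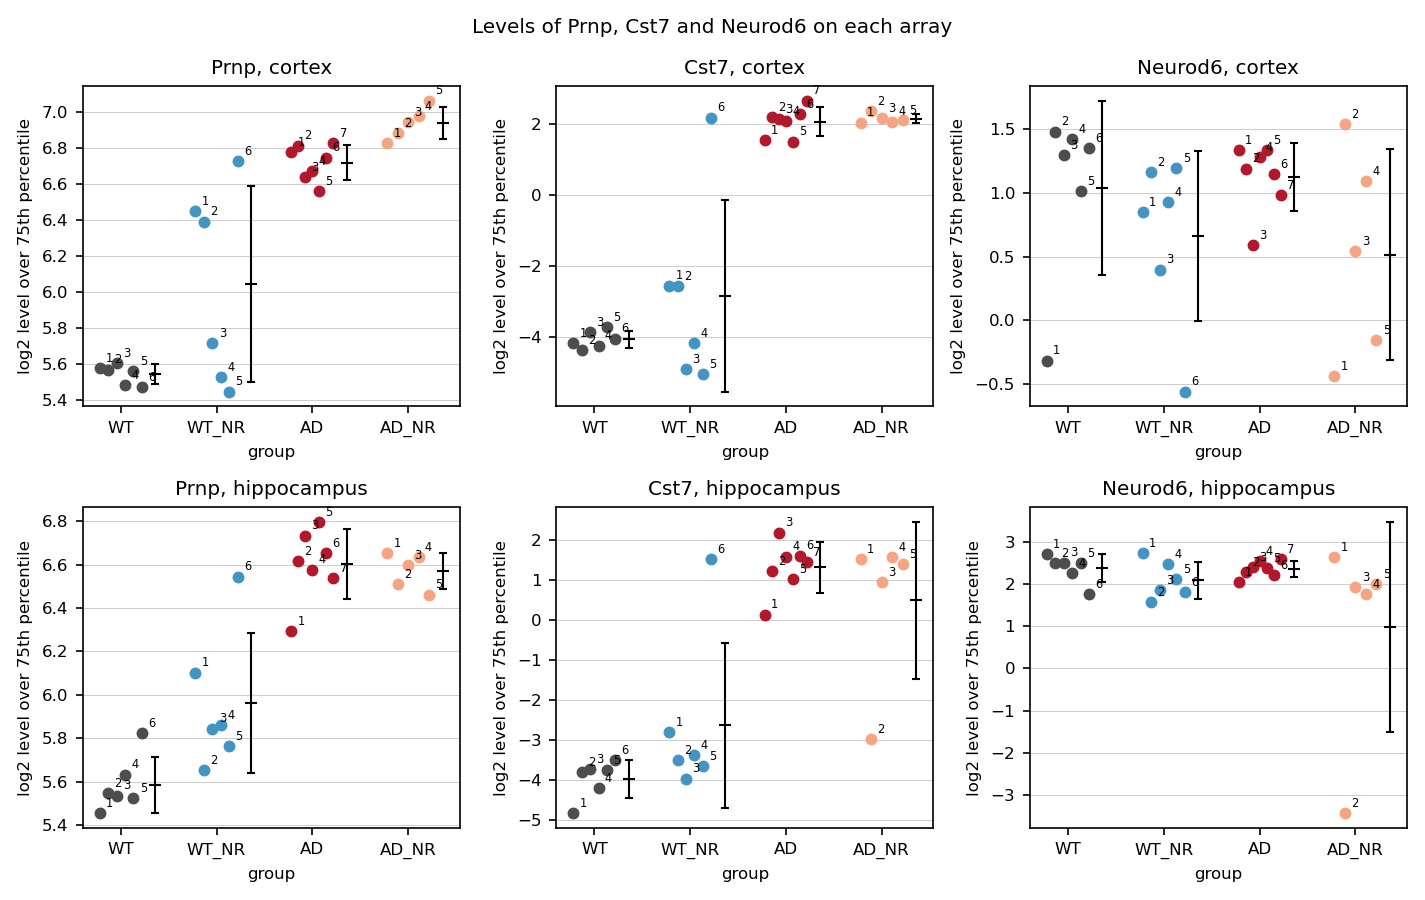
Log2 level relative to the 75th percentile of each array (vertical axis) of Prnp, Cst7 and Neurod6 on each array by group (horizontal axis), with points numbered by replicate and bars for the mean ± SD. The mouse labelled WT_NR replicate 6 lies at 6.73 for Prnp in the cortex among the AD arrays, and AD_NR replicate 2 of the hippocampus lies at -3.43 for Neurod6.

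The cortex of AD mice, compared with untreated WT mice to show what the transgenes change, was marked by a rise of genes of microglia near plaques. Cst7 rose by log2 6.13 ± 0.73 (adjusted p = 6.55e-05, n = 6 and 7 with limma), from -4.08 ± 0.24 in WT, where it was dim but well above background on 6 of 6 arrays, to 2.05 ± 0.41 in AD. Itgax rose by 5.20 ± 0.60, and the chemokines Ccl3, Ccl4 and Ccl6 rose by 4.68 ± 0.50, 4.48 ± 0.55 and 3.33 ± 0.47. Lilrb4a, an inhibitory receptor of myeloid cells, rose by 3.13 ± 0.43, Cxcl10, a chemokine induced by interferon, by 3.08 ± 0.63, and Gpnmb, a glycoprotein of phagocytes, by 2.56 ± 0.42. For each of these 8 genes all 7 AD arrays lay above all 6 WT arrays. Itgax and Ccl4 were well above background on 5 and 3 of the WT arrays, so the sizes of their rises are less certain. Prnp rose by 1.17 ± 0.16 (adjusted p = 0.000173). Among the named falls, Gm6588 fell by 1.97 ± 0.43, the thioesterase Acot12 by 1.66 ± 0.37, the activity-induced transcription factor Egr2 by 1.62 ± 0.31 and the vomeronasal receptor Vmn2r77 by 1.62 ± 0.44. Asb4 fell by 1.58 ± 0.39, Fam180a by 1.47 ± 0.40, the transcription factor Tshz2 by 1.42 ± 0.36 and the death receptor Tnfrsf25 by 1.41 ± 0.30. Of these, Gm6588, Acot12, Vmn2r77 and Fam180a were well above background on 3, 3, 2 and 4 of the 7 AD arrays, so the sizes and the order of these 4 falls are uncertain.

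In all, 1413 of 36825 genes passed the limma test, 393 higher and 1020 lower, and 5839 had an unadjusted p under 0.05. Of the named ones 345 were higher and 98 lower, so that 922 of the genes called lower carry no symbol. The count fell to 605 with quantile normalisation (403 higher, 202 lower), to 373 with normexp (296 higher, 77 lower), to 466 with z-scores per array (372 higher, 94 lower) and to 599 in the authors' table (392 higher, 207 lower). These scalings moved the median over all genes from -0.14 to -0.01, so small falls are relative to the scaling. Without the noisy arrays WT_NR 1 and 2 the count was 3396 (802 higher, 2594 lower), without the mouse labelled WT_NR replicate 6 it was 1292 (418 higher, 874 lower), and without all 3 it was 3418 (844 higher, 2574 lower). Leaving out 1 array moved it over 1.5 times for WT 1 (873), WT 2 (914), WT 3 (464), WT 4 (491), WT 5 (691), AD 1 (2357), AD 2 (509), AD 6 (492) and AD 7 (724).

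On slide 2, where 4 AD arrays lay beside 4 WT_NR arrays, 385 of the 393 genes had the same sign and a median of 0.56, and 978 of the 1020 had the same sign and a median of -0.29. The 4 AD arrays are among the 7 that chose these genes, so shared signs are partly built in. No gene passed limma there (828 at an unadjusted p under 0.05). Without the mouse labelled WT_NR replicate 6, 27 genes were higher on that slide, 25 of them among the 393, with Cst7 at 6.70 ± 0.26, Itgax at 5.14 ± 0.34 and Prnp at 1.16 ± 0.12. With slide as a fixed block, a fit that rests on the noisy WT_NR 1 and 2 as the link to WT, 14744 genes passed (11224 higher, 3520 lower, median over all genes 0.47). Of the 1413 genes 327 passed again and 1251 had the same sign. In that fit Cst7 differed by 6.49, Itgax by 4.50, Ccl3 by 5.05, Ccl6 by 1.34, Gpnmb by 1.83, Egr2 by -0.29 and Prnp by 1.75.

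Groups of microglia genes rose together in AD cortex. Of 29 genes of plaque-associated microglia 20 rose and none fell, 24 when adjusted over the list alone, with a median of 1.48; Tyrobp, the signalling adaptor of TREM2, rose by 2.17 ± 0.22. The list passed camera (adjusted p = 1.09e-51; adjusted p = 0.0013 with an estimated correlation). Of 15 genes of homeostatic microglia 9 rose (11 adjusted over the list alone). Among them the purine receptor P2ry13 rose by 0.99 ± 0.13, Selplg by 0.87 ± 0.13 and Gpr34 by 1.24 ± 0.19 (camera adjusted p = 2.05e-21; 0.000362 as adjusted p with an estimated correlation). Of 15 complement genes 7 rose (9 over the list alone), with the integrin chain Itgb2 at 1.32 ± 0.18, C4b at 1.95 ± 0.28, C1qa at 1.29 ± 0.20 and C1qc at 1.22 ± 0.21 (adjusted p = 2.68e-12; adjusted p = 0.0159 with an estimated correlation). Of 29 cytokine and inflammasome genes 11 rose (12 over the list alone), with the pattern receptors Cd14 at 1.84 ± 0.23 and Tlr2 at 1.46 ± 0.19 (adjusted p = 1.92e-16; adjusted p = 0.00977 with an estimated correlation). Of the 9 lists called in AD cortex with an estimated correlation, 2 were called again without the noisy WT_NR 1 and 2: cortex, AD vs WT: list homeostatic microglia (adjusted p = 0.00686) and cortex, AD vs WT: list plaque-associated microglia (DAM) (adjusted p = 0.00840). The other 7 ran from cortex, AD vs WT: list mitophagy and autophagy (adjusted p = 0.0507) to cortex, AD vs WT: list reactive astrocytes (adjusted p = 0.132). All 9 were called without all 3 arrays in doubt. On slide 2 the medians of AD minus WT_NR were 1.06, 0.20, 0.42 and 0.41 for the plaque-associated, homeostatic, complement and cytokine lists. Without the mouse labelled WT_NR replicate 6 they were 1.42, 0.28, 0.55 and 0.62 there. With slide as a fixed block the AD minus WT medians were 0.69, 0.76, 0.53 and 1.62, and camera no longer called any of them (adjusted p = 0.733, 0.241, 0.964 and 0.195).

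Interferon and antigen presentation genes were higher as well. Of 29 interferon-stimulated genes 9 rose (12 adjusted over the list alone), with Lgals3bp at 1.66 ± 0.26, Ifi27l2a at 2.11 ± 0.38 and Bst2, which tethers virus particles to the cell, at 1.21 ± 0.22 (camera adjusted p = 4.91e-23; adjusted p = 0.0347 with an estimated correlation). Of 13 antigen presentation genes 3 rose (7 over the list alone), the immunoproteasome subunit Psmb8 by 0.86 ± 0.22, H2-Ab1 by 1.32 ± 0.34 and its chaperone Cd74 by 1.36 ± 0.38, while the class I gene H2-D1 had 0.63 ± 0.19 (adjusted p = 0.0567). That list had a camera adjusted p of 4.77e-11 (adjusted p = 0.0347 with an estimated correlation). Of 20 genes of the cGAS-STING pathway, which senses DNA in the cytosol, 3 rose: the DNA sensors Ifi204 (1.53 ± 0.29) and Aim2 (0.50 ± 0.13) and the adaptor Sting1 (0.46 ± 0.11, adjusted p = 0.0235). Over the list alone, 3 were higher and 1 lower. Cgas itself differed by 0.22 ± 0.14 (adjusted p = 0.508) and Ifnar1 by -0.56 ± 0.18 (adjusted p = 0.0749). The pathway's median was -0.01 and its mean 0.05, yet camera placed it above the other genes, whose median was -0.14 (adjusted p = 0.00562; adjusted p = 0.113 with an estimated correlation). On slide 2 the medians of the interferon, antigen presentation and cGAS-STING lists were 0.55, 0.35 and 0.10. Without the mouse labelled WT_NR replicate 6 they were 0.77, 0.69 and 0.19 there. With slide as a fixed block and all arrays they were 0.63, 0.84 and 0.41, with camera adjusted p of 0.924, 0.922 and 0.924.

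The lists of reactive astrocytes, senescence and activity genes held fewer passing genes than the list of plaque-associated microglia. Of 20 genes of reactive astrocytes 5 rose (9 adjusted over the list alone), with Gfap at 1.76 ± 0.30, the oncostatin M receptor Osmr at 1.27 ± 0.28 and the protease inhibitor Serpina3n at 1.58 ± 0.37 (list median 0.41, camera adjusted p = 1.88e-09; adjusted p = 0.0424 with an estimated correlation). The list median was 0.29 on slide 2, or 0.44 without the mouse labelled WT_NR replicate 6. It was also 0.44 with slide as a fixed block, where Gfap differed by 1.10 and Serpina3n by -0.28. With that block the list lay below the all-gene median of 0.47 and was no longer called (cortex, AD vs WT: list reactive astrocytes, adjusted p = 0.254). Of 26 genes of senescence and its secreted factors 1 rose, the urokinase receptor Plaur (0.77 ± 0.21, adjusted p = 0.0464), and over the list alone 4 were higher and 1 lower (median 0.08, camera adjusted p = 0.00114; adjusted p = 0.124 with an estimated correlation). On slide 2 its median was 0.12, or 0.22 without the mouse labelled WT_NR replicate 6. With the slide block it was 0.65 and the camera call ended (cortex, AD vs WT: list senescence and SASP, adjusted p = 0.964). The cell cycle inhibitors Cdkn2a (0.07 ± 0.21) and Cdkn1a (-0.35 ± 0.30) and the cytokines Tnf (0.06 ± 0.28), Il1b (-0.27 ± 0.36) and Il6 (0.58 ± 0.25) did not pass, with adjusted p from 0.231 to 0.935. Of 19 immediate early genes, which neurons switch on with activity, 4 fell (9 over the list alone): Egr2, Egr4 by 0.90 ± 0.20, Fosl2 by 0.82 ± 0.19 and Nr4a1 by 1.13 ± 0.29. Their list median was -0.53 (camera adjusted p = 8.47e-05; adjusted p = 0.238 with an estimated correlation) and -0.45 on slide 2, where 1 of 19 was above 0; with slide as a fixed block Nr4a1 differed by 0.02 and the list median was -0.29.

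Other lists that passed camera held few or no passing genes. NAD metabolism (33 genes, none past, median 0.06, adjusted p = 0.00825; adjusted p = 0.0319 with an estimated correlation) lay above the other genes. Mitophagy and autophagy did too (27 genes, with the lysosomal membrane gene Lamp2 up by 0.44 ± 0.11, list median 0.06, adjusted p = 0.00114; adjusted p = 0.0270 with an estimated correlation). The same held for oxidative phosphorylation (median 0.03, adjusted p = 0.000969; adjusted p = 0.329 with an estimated correlation) and general astrocyte genes (0.09, adjusted p = 0.00814; adjusted p = 0.221 with an estimated correlation). With slide as a fixed block 2 of these turned below the other genes: cortex, AD vs WT: list mitophagy and autophagy (median -0.02, adjusted p = 0.0123) and cortex, AD vs WT: list astrocytes (-0.24, adjusted p = 0.00403). With slide and array column cortex, AD vs WT: Lamp2 was -0.0747. The slide block also ended the calls of cortex, AD vs WT: list NAD metabolism (adjusted p = 0.239) and cortex, AD vs WT: list oxidative phosphorylation (adjusted p = 0.980). With quantile normalisation camera no longer called the cGAS-STING (adjusted p = 0.0574), mitophagy (0.503), oxidative phosphorylation (0.459) and astrocyte (0.459) lists. Genes of tissues beside the cortex also lay higher: choroid plexus (median 0.55, adjusted p = 0.000562; adjusted p = 0.343 with an estimated correlation), and striatum (0.55, adjusted p = 0.000498; adjusted p = 0.377 with an estimated correlation). So did the hippocampus region (0.15, adjusted p = 0.0292; adjusted p = 0.286 with an estimated correlation). On slide 2 their medians were -0.22, -0.09 and 0.22, and on that slide NAD metabolism and mitophagy both had 0.01.

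The remaining 17 lists did not pass camera in AD cortex. Lists placed above the other genes were neurogenesis and proliferation (median -0.02, mean 0.04, adjusted p = 0.0813), heat shock and chaperones (median 0.03, 0.0813), and DNA repair (0.01, 0.0813). The unfolded protein response (0.02, adjusted p = 0.0541), synapse (median 0.03, mean -0.01, 0.0616), mitochondrial biogenesis (median 0.02, mean -0.01, 0.114) and T cells and neutrophils (median -0.07, mean 0.08, 0.109) lay above them as well. So did neurons (0.00, adjusted p = 0.107), interneurons (-0.02, 0.411), oligodendrocytes (-0.06, 0.175), thalamus (median -0.13, mean 0.01, 0.175) and the cortex region (-0.10, 0.475), with a median over all genes of -0.14. Blood had a median of -0.41 and a mean of -0.45, below that of all genes, while camera, which compares moderated t values, placed it above them (adjusted p = 0.971). Endothelium (-0.24, adjusted p = 0.0813), meninges (-0.37, 0.345), the circadian clock (-0.17, 0.0813) and sex-linked genes (-1.06, 0.917) lay below the others. By score per mouse endothelium and the clock were both 0.22 lower in AD (exact permutation adjusted p = 0.00660 and 0.0357). With quantile normalisation camera called them too: cortex, AD vs WT: list endothelium and mural cells (adjusted p = 0.00278) and cortex, AD vs WT: list circadian clock (adjusted p = 0.000721). Their medians were -0.20 and -0.05 on slide 2, or -0.23 and -0.10 without the mouse labelled WT_NR replicate 6. The slide block gave -0.35 and -0.34, and camera called both (adjusted p = 0.000152 and 0.00158). Single genes of these lists rose, the T cell chemokine Ccl5 by 1.59 ± 0.33, the steroid-induced cochaperone Fkbp5 by 0.71 ± 0.17 and the actin-binding Synpo2 of the thalamus list by 0.82 ± 0.13.

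In the hippocampus of AD mice, compared with WT mice to see whether it changes as the cortex does, the same microglia genes led a shorter list. Cst7 rose by log2 5.30 ± 0.75 (adjusted p = 0.00466, n = 6 and 7 with limma), Itgax by 3.35 ± 0.57, and Ccl3, Ccl4 and Ccl6 by 3.26 ± 0.57, 2.92 ± 0.55 and 2.31 ± 0.40. Of these 5 genes only Ccl4, with 5, was not well above background on all 6 WT arrays. The lipid droplet protein gene Plin4 rose by 2.14 ± 0.32, the proton-sensing receptor Gpr65 by 1.99 ± 0.36 and C3ar1, receptor of a complement fragment, by 1.78 ± 0.28. The growth factor Igf1 rose by 1.41 ± 0.22, Cd14 by 1.22 ± 0.22, Itgb2 by 1.08 ± 0.15 and Prnp by 1.02 ± 0.12. The kinase gene Sik1 fell by 0.59 ± 0.10 (adjusted p = 0.0244) and the clock gene Per1 by 0.53 ± 0.10 (adjusted p = 0.0361). These 2 were the only falls among 22 genes that passed of 38149, and 4523 had an unadjusted p under 0.05. With slide as a fixed block no gene passed limma (3498 at an unadjusted p under 0.05), with Cst7 at 4.48, Itgax at 2.90, Ccl3 at 3.32, Plin4 at 2.60, C3ar1 at 2.18 and Prnp at 0.84. That fit links the slide of WT to that of AD through WT_NR arrays. The noisy WT_NR 1 and the mouse labelled WT_NR replicate 6 are among these, so the loss of calls cannot be put down to slide alone. On slide 5, AD beside WT_NR, all 20 higher and both lower genes had the same sign and none passed limma (3246 at an unadjusted p under 0.05). Here too the AD arrays are among those that chose the genes.

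The hippocampus count depended on the arrays in doubt: 19 without the noisy WT_NR 1 (17 higher, 2 lower) and 157 without AD 1 as well (149 higher, 8 lower). It was 103 without the mouse labelled WT_NR replicate 6 and AD_NR 2 (90 higher, 13 lower) and 305 without all 4 (279 higher, 26 lower). Leaving out 1 array gave 8 without WT 1, WT 3 or AD 7, 9 without WT 2, WT 5, AD 2, AD 3, AD 4 or AD 6, 10 without WT 4 and 13 without AD_NR 3. It gave 2495 without WT 6, 64 without WT_NR 6, 143 without AD 1 and 69 without AD_NR 2. Cst7, Prnp, Plin4, C3ar1, Itgb2 and Igf1 passed in each of these fits.

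Upward, 8 hippocampus lists passed camera in AD mice, and none of them with an estimated correlation. Of 29 genes of plaque-associated microglia 6 rose (20 adjusted over the list alone), with a list median of 0.74 (camera adjusted p = 1.68e-19; adjusted p = 0.157 with an estimated correlation, 0.0118 without the 4 arrays in doubt). Its median was 0.67 on slide 5, or 0.997 without the mouse labelled WT_NR replicate 6, and 0.65 with slide as a fixed block. Homeostatic microglia had no passing gene and 10 over the list alone (median 0.46, camera adjusted p = 7.14e-08; adjusted p = 0.228 with an estimated correlation), with the receptor Csf1r at 0.61 ± 0.14. Complement had 2 rises, Itgb2 and C3ar1, and 6 over the list alone (median 0.23, adjusted p = 7.25e-06; adjusted p = 0.236 with an estimated correlation). Cytokines had 3, and 7 over the list alone (median 0.45, adjusted p = 1.46e-07; adjusted p = 0.307 with an estimated correlation). Reactive astrocytes had none and 6 over the list alone (median 0.27, adjusted p = 0.00197; adjusted p = 0.405 with an estimated correlation), with Gfap at 0.79 ± 0.20 and C4b at 1.15 ± 0.26. Interferon-stimulated genes had none (median 0.45, adjusted p = 2.61e-07; adjusted p = 0.520 with an estimated correlation). Antigen presentation had none and 1 over the list alone (median 0.44, adjusted p = 0.0015; adjusted p = 0.539 with an estimated correlation). Senescence genes had a median of 0.27 (adjusted p = 0.0439; adjusted p = 0.539 with an estimated correlation), with Cdkn2a at 0.42 ± 0.22 and Cdkn1a at 0.05 ± 0.23. The cGAS-STING list did not pass (median 0.10, adjusted p = 0.171), with 2 genes higher over the list alone, Ifnb1 at 1.32 ± 0.39 and Ifi204 at 0.96 ± 0.30, Sting1 at 0.29 ± 0.13 and Cgas at 0.09 ± 0.12. On slide 5 the medians of the homeostatic, complement, cytokine, astrocyte, interferon, antigen presentation and senescence lists were 0.21, 0.52, 0.30, 0.26, 0.30, 0.41 and 0.08. Without the mouse labelled WT_NR replicate 6 they were 0.25, 0.69, 0.42, 0.42, 0.47, 0.67 and 0.10 there. With slide as a fixed block and all arrays they were 0.53, 0.63, 0.48, 0.38, 0.45, 0.43 and 0.29. Tnf had 0.31 ± 0.24, Il1b 0.21 ± 0.24 and Il6 0.45 ± 0.28.

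Downward, 7 hippocampus lists passed camera in AD mice, and none of them with an estimated correlation. Immediate early genes had a median of -0.37 (camera adjusted p = 4.21e-06, adjusted p = 0.330 with an estimated correlation). It was -0.14 on slide 5, or -0.25 without the mouse labelled WT_NR replicate 6, and 0.24 with slide as a fixed block. The circadian clock had -0.11 (camera adjusted p = 7.67e-06, adjusted p = 0.0835 with an estimated correlation). Its median was -0.09 on slide 5, or -0.16 without the mouse labelled WT_NR replicate 6, and -0.07 with the slide block. DNA repair (-0.01, adjusted p = 0.00783; adjusted p = 0.330 with an estimated correlation) lay below an all-gene median of 0.07. So did mitochondrial biogenesis (-0.03, adjusted p = 0.0439; adjusted p = 0.330 with an estimated correlation) and heat shock (-0.01, adjusted p = 0.0276; adjusted p = 0.539 with an estimated correlation). So did meninges (-0.12, camera adjusted p = 0.0310, adjusted p = 0.720 with an estimated correlation) and the cortex region (-0.17, adjusted p = 0.0446, adjusted p = 0.539 with an estimated correlation). On slide 5 without the mouse labelled WT_NR replicate 6, DNA repair, mitochondrial biogenesis and heat shock had medians of -0.07, -0.10 and -0.21. Meninges and the cortex region had 0.12 and 0.01 there, no longer below 0.

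**Figure D2:**
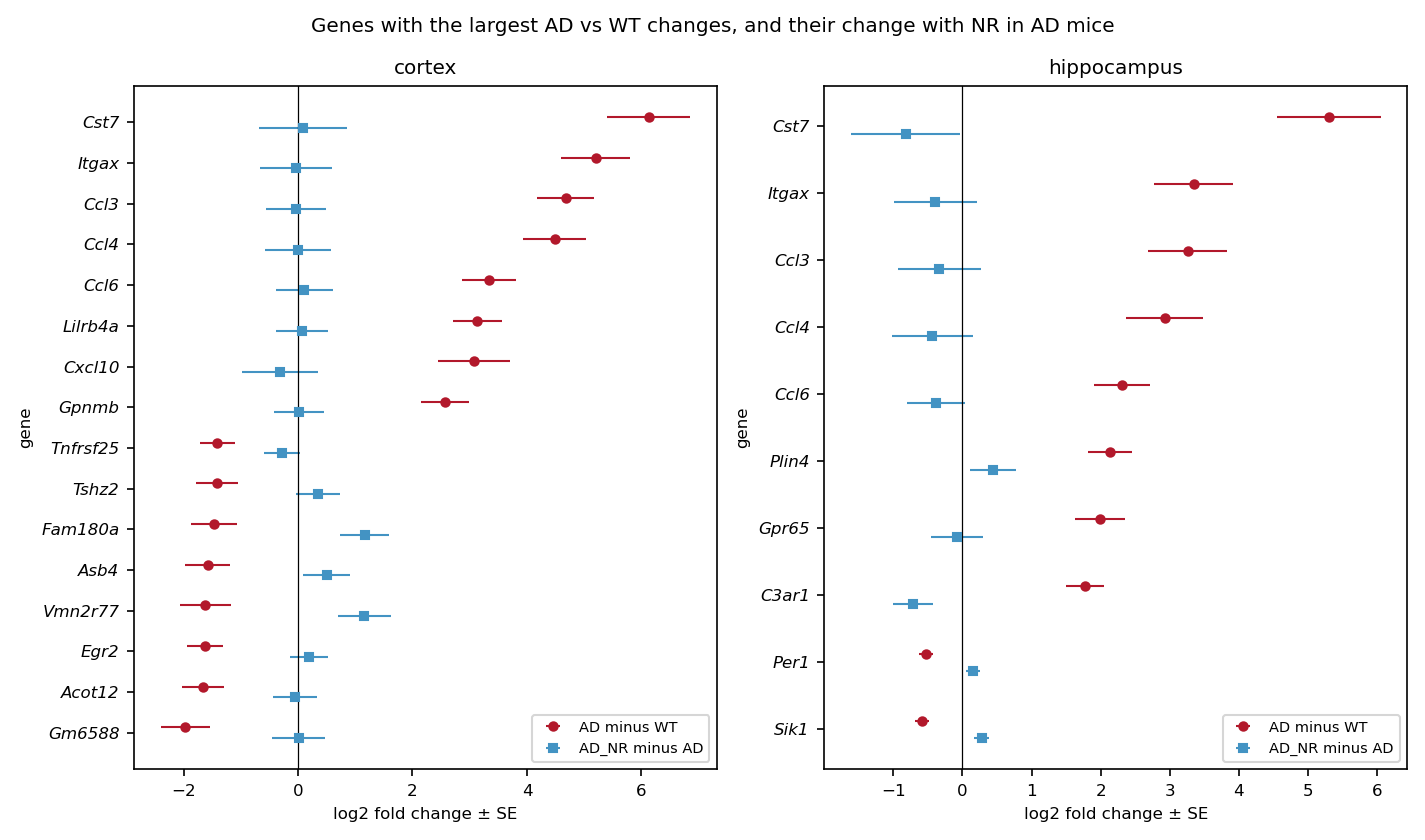
Log2 fold change ± SE (horizontal axis) of the genes with the largest AD minus WT changes in each region (vertical axis), with the AD_NR minus AD difference of the same genes. Cst7 lies at 6.13 for AD and 0.09 for NR in the cortex, and at 5.30 and -0.82 in the hippocampus.

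NR in AD mice, the comparison that asks whether the treatment alters the AD brain, gave no difference past the threshold in the genes raised in AD cortex. Cst7 differed between AD_NR and AD by 0.09 ± 0.76 (n = 5 and 7), Itgax by -0.03 ± 0.63, Ccl3 by -0.04 ± 0.53, Ccl4 by 0.00 ± 0.58 and Ccl6 by 0.11 ± 0.50. Lilrb4a differed by 0.08 ± 0.46, Cxcl10 by -0.31 ± 0.66 and Gpnmb by 0.02 ± 0.44. These standard errors use the spread within all 4 groups. Cortex Cst7 ran from 1.49 to 2.65 in AD and from 2.03 to 2.35 in AD_NR. In WT_NR it was 2.17 on replicate 6 and -5.06 to -4.19 on replicates 3 to 5, which widens its standard error. Of the AD falls, Egr2 differed by 0.19 ± 0.33, Gm6588 by 0.01 ± 0.46, Acot12 by -0.05 ± 0.39 and Asb4 by 0.50 ± 0.41. Tshz2 differed by 0.35 ± 0.38, Tnfrsf25 by -0.28 ± 0.32, Vmn2r77 by 1.16 ± 0.47 and Fam180a by 1.16 ± 0.42. With the AD arrays divided, the NR difference of the AD genes, counted along their AD change of 1.19, had a median of 0.11 over 70 choices (-0.06 to 0.43). These came from 35 divisions, each used both ways, and 8 of the 70 lay below 0, the sign of a return toward WT. The 70 choices share their arrays and are not independent, and the all-gene median of AD_NR minus AD was 0.08. With the AD arrays undivided the cortex median was 0.06. Of 99 random redraws of the AD and AD_NR labels, 72 gave a value at or below it (range -0.48 to 0.21). In the hippocampus Cst7 differed by -0.82 ± 0.79, Itgax by -0.40 ± 0.60, Ccl3 by -0.34 ± 0.60, Ccl4 by -0.43 ± 0.58 and Ccl6 by -0.39 ± 0.42. Plin4 differed by 0.44 ± 0.33, Gpr65 by -0.08 ± 0.37, C3ar1 by -0.71 ± 0.29, Sik1 by 0.28 ± 0.11 and Per1 by 0.15 ± 0.10, all short of the threshold. In the hippocampus 59 of the 70 choices gave genes, with a median of 1 gene per choice over all 70. The median difference was -0.003 (-0.46 to 0.49), with 30 below 0, which rests on too few genes to show a direction. Without all arrays in doubt the cortex median was 0.09 (-0.11 to 0.31), with 14 of 70 choices below 0. In the hippocampus all 40 choices then gave genes, with a median of -0.002 (-0.12 to 0.13) along an AD change of 0.93, and 20 lay below 0. The 6 AD arrays left there divide into equal parts, so the 40 hold each distinct choice in duplicate. Without the 4 arrays in doubt, AD_NR 2 among them, Cst7 differed by -0.15 ± 0.24, Itgax by 0.03 ± 0.25 and C3ar1 by -0.26 ± 0.17. Within slides 3 and 6, the latter without AD_NR 2, Cst7 differed by 0.00 ± 0.24 and 0.00 ± 0.21.

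No gene passed limma for NR in AD mice in either region, with 1007 at an unadjusted p under 0.05 in the cortex (smallest adjusted p = 0.99999) and 4334 in the hippocampus (smallest adjusted p = 0.223). Both counts stayed at 0 without all arrays in doubt, and within slides 3 and 6, which held both groups, they were 0 with 4268 and 1447 at an unadjusted p under 0.05. In the hippocampus 38 genes passed with the filter on all arrays, 6500 with array weights, 380 without AD_NR 1 and 1 without AD 1. The smallest p in the cortex belonged to Allc (0.74 ± 0.22), the glucagon gene Gcg (0.91 ± 0.28) and the potassium channel Kcnk9 (0.77 ± 0.24) upward and to A330070K13Rik (-0.65 ± 0.19), Smg8 (-0.42 ± 0.14) and Map3k20 (-0.57 ± 0.21) downward. In the hippocampus they were Nat8f5 (0.44 ± 0.09), Txndc15 (0.35 ± 0.07) and 1110046J04Rik (0.46 ± 0.10), and the kinase Map3k3 (-0.65 ± 0.13), Leng8 (-0.59 ± 0.14) and the receptor Igf1r (-0.55 ± 0.14).

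Of the lists closest to the question, only interferon-stimulated genes passed for NR in AD mice, lower in the cortex (median -0.05, adjusted p = 0.0112; adjusted p = 0.861 with an estimated correlation). The all-gene median was 0.08 in both regions. In the cortex plaque-associated microglia had a median of 0.06 and a mean of 0.08, placed below the other genes (adjusted p = 0.763), and the cGAS-STING pathway 0.06 (adjusted p = 0.816). Medians were 0.11 for senescence (adjusted p = 0.763), 0.12 for homeostatic microglia (0.708) and 0.17 for complement (0.484). Cytokines had a median of 0.07 and a mean of 0.10 and were placed below the others (0.794), as was NAD metabolism with 0.04 and 0.06 (0.763). In the hippocampus plaque-associated microglia had a median of -0.15 (adjusted p = 0.290), a value that AD_NR 2 carries. It was 0.05 without the arrays against their labels (adjusted p = 0.766) and -0.08 without all arrays in doubt (adjusted p = 0.560), where the score difference went from -0.15 to -0.04. The medians were 0.09 for cGAS-STING (0.913), 0.08 for senescence (0.913), 0.08 for cytokines (0.819), 0.08 for interferon-stimulated genes (0.819) and 0.06 for NAD metabolism (0.970). Within slides 3 and 6 the medians of plaque-associated microglia were 0.03 and -0.16, of cGAS-STING 0.07 and 0.07, and of senescence 0.13 and 0.11. Within slide 6 without AD_NR 2 they were 0.08, 0.04 and 0.16. Over the list alone, the cGAS-STING list held 3 hippocampus genes past the threshold, the RNase H2 subunits Rnaseh2b (0.29 ± 0.08) and Rnaseh2c (0.26 ± 0.08) higher and the interferon receptor Ifnar1 (-0.58 ± 0.16) lower. Sting1 differed by 0.07 ± 0.12 in the cortex and -0.21 ± 0.14 in the hippocampus, and Cgas by 0.12 ± 0.15 and -0.13 ± 0.13. Cdkn2a differed by 0.40 ± 0.22 and 0.26 ± 0.23 and Cdkn1a by 0.35 ± 0.31 and 0.68 ± 0.24. The cytokines gave 0.16 ± 0.29 and -0.07 ± 0.25 for Tnf, 0.59 ± 0.38 and 0.28 ± 0.25 for Il1b, and 0.37 ± 0.26 and 0.22 ± 0.29 for Il6. NAD genes with the smallest p were Bst1, an ectoenzyme that uses NAD, in the cortex (0.65 ± 0.26) and the mitochondrial NAD kinase Nadk2 (0.28 ± 0.09) and the deacylase Sirt5 (0.28 ± 0.10) in the hippocampus.

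Of 34 lists, 8 passed camera for NR in AD cortex and 7 in the hippocampus, and none of the 15 with an estimated correlation. Oxidative phosphorylation lay higher in both. In the cortex its median was 0.11, with 43 of 45 genes above 0 (camera adjusted p = 0.00356, adjusted p = 0.861 with an estimated correlation). The all-gene median was 0.08 in both regions, so most genes lay above 0. In the hippocampus the list median was 0.18, with 42 of 45 above 0 (camera adjusted p = 1.75e-09, adjusted p = 0.914 with an estimated correlation). Without all arrays in doubt it was 0.10 there (camera adjusted p = 5.99e-06, adjusted p = 0.764 with an estimated correlation). AD_NR 2 had the highest score of this list there, 0.31 against at most 0.27 elsewhere. The score difference went from 0.17 to 0.09 without the arrays in doubt (exact permutation p = 0.0126 and 0.0571). The list medians were 0.14 and 0.12 within slides 3 and 6, against all-gene medians of 0.13 and 0.07. Without AD_NR 2 the list median within slide 6 was 0.06. Its genes with the smallest p in the hippocampus were the cytochrome gene Cyc1 (0.39 ± 0.10) and Sdha (0.30 ± 0.09). With quantile normalisation the cortex call ended (adjusted p = 0.945). In the hippocampus mitochondrial biogenesis (0.16, adjusted p = 0.0227; adjusted p = 0.717 with an estimated correlation), mitophagy (0.05, adjusted p = 0.0267; adjusted p = 0.923 with an estimated correlation) and the unfolded protein response (0.12, adjusted p = 0.0227; adjusted p = 0.923 with an estimated correlation) also lay higher. Lower were synapse (-0.19, adjusted p = 8.91e-06; adjusted p = 0.874 with an estimated correlation), the hippocampus region (-0.75, adjusted p = 9.77e-07; adjusted p = 0.717 with an estimated correlation) and choroid plexus (-1.52, adjusted p = 9.77e-07; adjusted p = 0.923 with an estimated correlation). Within slide 6 these 6 lists had medians of 0.13, 0.06, 0.14, -0.31, -0.63 and -0.68, and without AD_NR 2 of 0.09, 0.02, 0.12, -0.12, -0.28 and -0.19. The array AD_NR 2, whose hippocampus region score was -2.24, is among the arrays. Without all arrays in doubt the 6 medians were 0.11, 0.03, 0.12, -0.12, -0.45 and -1.32, with adjusted p of 0.00240, 0.0275, 0.0421, 0.0275, 0.00240 and 0.00240. The score differences of synapse and the hippocampus region then went from -0.21 to -0.08 and from -0.72 to -0.37. In the cortex, endothelium (-0.14, adjusted p = 5.82e-07; adjusted p = 0.262 with an estimated correlation) and DNA repair (-0.03, adjusted p = 0.00289; adjusted p = 0.142 with an estimated correlation) lay lower. Interferon-stimulated genes and oligodendrocytes (-0.09, adjusted p = 0.0309; adjusted p = 0.861 with an estimated correlation) did as well. So did striatum (-0.40, adjusted p = 0.00103; adjusted p = 0.861 with an estimated correlation) and the cortex region (-0.15, adjusted p = 0.00103; adjusted p = 0.712 with an estimated correlation). Meninges lay higher (0.49, adjusted p = 0.00296; adjusted p = 0.861 with an estimated correlation). Within slide 3 these 7 lists had medians of -0.23, -0.01, -0.02, 0.16, 0.52, -0.20 and 0.04. With slide as a fixed block camera placed meninges below the other genes (cortex, NR vs untreated in AD: list meninges and fibroblasts, adjusted p = 0.0473).

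Scores per mouse gave 0 of 34 lists past an exact permutation test of AD_NR against AD in either region, with 6 cortex and 4 hippocampus lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.215 in both. With all arrays in doubt left out these were 0 lists again, 6 and 1 at an unadjusted p under 0.05, and smallest adjusted p of 0.215 and 0.648. The cGAS-STING score was 0.13 higher in AD_NR cortex (exact permutation p = 0.0278, adjusted p = 0.222). Within slide 3 it was 0.17 higher with all 5 AD_NR above the 3 AD arrays, p = 0.0179 by exact permutation, the smallest that 56 splits can give (adjusted p = 0.607). The all-gene median was also higher in AD_NR, by 0.08 in the cortex and by 0.13 within slide 3. Scores are not corrected for such a shift, and the median of the list within slide 3 was 0.07. For comparison, the score of plaque-associated microglia was 0.82 ± 0.22 in AD and -0.98 ± 0.07 in WT cortex (SD, n = 7 and 6, exact permutation adjusted p = 0.00396, 7 of 7 above all WT).

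**Figure D3:**
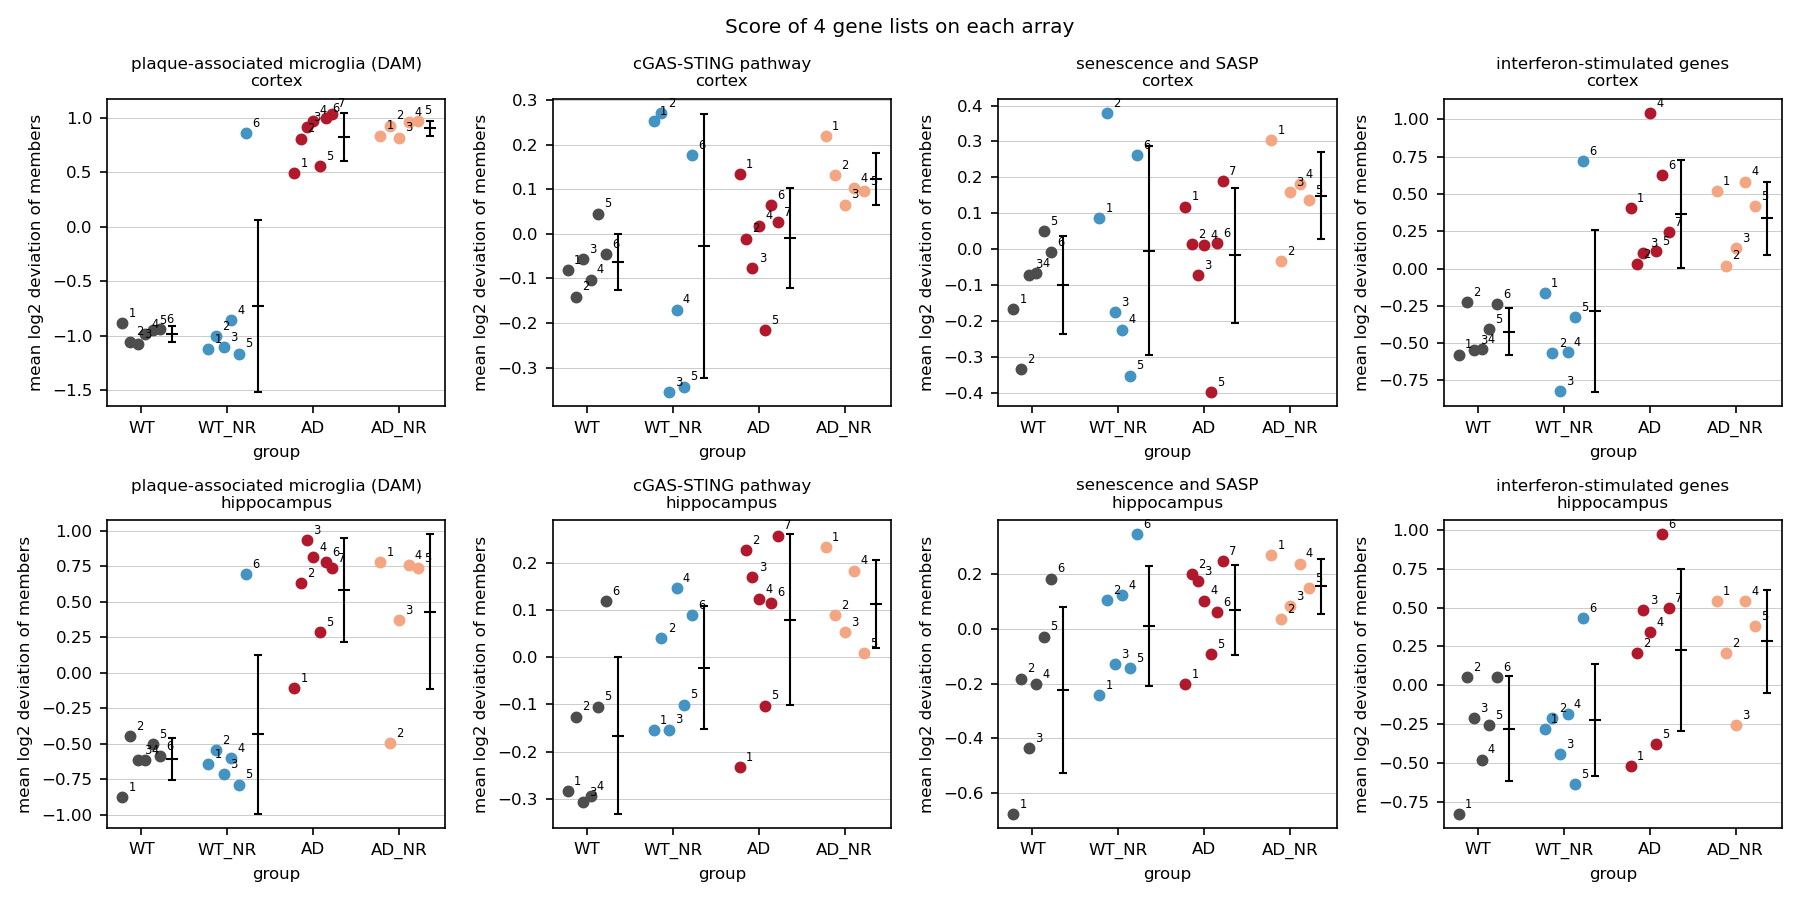
Score per array (vertical axis, mean centred log2 value of the list) of plaque-associated microglia, cGAS-STING, senescence and interferon-stimulated genes by group (horizontal axis) in both regions. In the cortex the score of plaque-associated microglia is 0.82 ± 0.22 in AD and -0.98 ± 0.07 in WT, and the mouse labelled WT_NR replicate 6 lies at 0.86.

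NR in WT mice, which asks what the treatment does without plaques, rests on groups in which WT_NR 1 and 2 of the cortex and WT_NR 1 of the hippocampus were noisy and the mouse labelled WT_NR replicate 6 had AD levels of Prnp and microglia genes. The smallest p in the cortex belonged to Scube1 (0.98 ± 0.17), 2700069I18Rik (1.12 ± 0.20) and the thioesterase Acot5 (0.73 ± 0.14) upward and to Gm10432 (-0.76 ± 0.15), Tshz2 (-1.88 ± 0.38) and the adhesion gene Tenm2 (-0.92 ± 0.20) downward. Among those of the hippocampus were the sodium pump subunit Atp1a4 (1.54 ± 0.35) and Gpr17 (0.45 ± 0.10), and Nkapl (-0.85 ± 0.24), Hhatl (-0.81 ± 0.26) and Mboat1 (-1.08 ± 0.36). None passed limma: 0 genes in the cortex (4376 at an unadjusted p under 0.05, smallest adjusted p = 0.180) and 0 in the hippocampus (5497, smallest adjusted p = 0.341). Sting1 differed by 0.30 ± 0.11 in the cortex and 0.05 ± 0.13 in the hippocampus, and Cgas by 0.16 ± 0.15 and 0.12 ± 0.13. Cdkn2a differed by 0.52 ± 0.21 and 0.51 ± 0.23, Cdkn1a by 0.01 ± 0.31 and 0.50 ± 0.24, and Tnf by 0.76 ± 0.29 and 0.40 ± 0.25. Without all arrays in doubt 3 genes passed in the cortex and 1 in the hippocampus, without the noisy ones 1 and 1, and without the mouse labelled WT_NR replicate 6 none. In the cortex fits without the noisy arrays, all WT_NR arrays lay on slide 2 and all WT arrays on slide 1. NR and slide cannot be told apart there. Leaving out 1 array gave 1 cortex gene without WT 1, and 5004 hippocampus genes without WT 6 and 1 without WT_NR 1. Within slide 1, where the 2 WT_NR arrays are the noisy ones, 18527 genes passed, and within slide 4 none did (2100 at an unadjusted p under 0.05).

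For NR in WT mice 7 lists passed camera in each region and none with an estimated correlation. In the cortex homeostatic microglia lay higher (median 0.32, 15 of 15 above 0, adjusted p = 4.08e-06; adjusted p = 0.167 with an estimated correlation), with Selplg at 0.62 ± 0.13 and P2ry12 at 0.91 ± 0.25, a group in which the mouse labelled WT_NR replicate 6 takes part. The unfolded protein response (0.24, adjusted p = 0.00419; adjusted p = 0.508 with an estimated correlation), heat shock (0.14, adjusted p = 0.0425; adjusted p = 0.508 with an estimated correlation), and cytokines (0.31, adjusted p = 0.0432; adjusted p = 0.885 with an estimated correlation) also lay higher. So did striatum (1.28, adjusted p = 0.000958; adjusted p = 0.885 with an estimated correlation). Lower were endothelium (-0.15, adjusted p = 0.0105; adjusted p = 0.885 with an estimated correlation) and the clock (-0.12, adjusted p = 0.0410; adjusted p = 0.584 with an estimated correlation). On slide 1 these 7 lists had medians of 0.33, 0.46, 0.31, 0.51, 0.49, -0.22 and -0.27 against 0.42 over all genes, so homeostatic microglia and heat shock lay below the other genes there. All 7 hippocampus lists lay below an all-gene median of 0.14: choroid plexus (-0.87, adjusted p = 4.34e-06), oligodendrocytes (-0.30, 0.000866), meninges (-0.16, 0.00248), and the hippocampus region (-0.17, 0.00494). The others were the cortex region (-0.06, adjusted p = 0.00817), thalamus (-0.05, 0.0157) and immediate early genes (-0.06, 0.0267). All 7 had adjusted p from 0.527 to 0.638 with an estimated correlation. With quantile normalisation none of these 7 passed, and on slide 4 their medians were -1.29, 0.02, 0.11, 0.08, 0.00, 0.09 and 0.29, against 0.24 over all genes.

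The interaction asks whether NR acted differently in AD and WT mice, and its WT side again includes the mouse labelled WT_NR replicate 6 and the noisy arrays. No gene passed limma in the cortex (1228 at an unadjusted p under 0.05, smallest adjusted p = 0.934) or the hippocampus (1575, smallest adjusted p = 0.817). The smallest p in the cortex belonged to Tshz2 (2.23 ± 0.54), B330016D10Rik (0.52 ± 0.13) and Gm10432 (0.82 ± 0.22) upward and Map3k20 (-1.36 ± 0.29), the proton pump subunit Atp6v0a4 (-1.11 ± 0.24) and P2ry14 (-0.65 ± 0.15) downward. In the hippocampus they were Slc25a2 (0.86 ± 0.24), Cyp2e1 (1.52 ± 0.43) and C1d (0.57 ± 0.16), and Zbtb16 (-0.71 ± 0.16), the DNA-dependent kinase Prkdc (-0.50 ± 0.12) and Adap2 (-0.61 ± 0.15). Without all arrays in doubt 167 cortex genes passed (166 higher, 1 lower) and none in the hippocampus. The 3 cortex WT_NR arrays left lay on slide 2 and all WT arrays on slide 1. The WT side of that cortex fit thus cannot be told apart from a slide difference. Of 34 lists 7 passed camera in the cortex and 10 in the hippocampus, none with an estimated correlation. The smallest p belonged in the cortex to striatum (median -1.51, adjusted p = 4.04e-08; adjusted p = 0.707 with an estimated correlation), meninges (0.74, adjusted p = 0.000142; adjusted p = 0.942 with an estimated correlation) and homeostatic microglia (-0.24, adjusted p = 5.72e-05; adjusted p = 0.397 with an estimated correlation). They had 0.11, 0.56 and -0.28 with slide as a fixed block. In the hippocampus oxidative phosphorylation (0.08, adjusted p = 0.000103; adjusted p = 0.694 with an estimated correlation), thalamus (0.31, adjusted p = 0.000156; adjusted p = 0.445 with an estimated correlation) and meninges (0.55, adjusted p = 0.000964; adjusted p = 0.694 with an estimated correlation) came first. Their medians were -0.05, 0.22 and 0.15 with slide as a fixed block. The AD side includes AD_NR 2, with a thalamus score of 1.57 against -0.38 to 0.21 elsewhere. Without all arrays in doubt the thalamus median was 0.14 (adjusted p = 0.0170; adjusted p = 0.221 with an estimated correlation), and its AD_NR minus AD score difference went from 0.32 to -0.03.

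Between the regions, the AD changes shared their risen genes. All 21 genes higher in the hippocampus over the 36357 shared genes were among the 386 higher in the cortex, where independence would give 0.223. Both genes lower in the hippocampus were among the 1002 lower in the cortex, where independence would give 0.0551. Cst7, Itgax, Ccl3 and Prnp are among the genes higher in both regions, and Per1 is among those lower in both. The values for independence are not the chance level of this overlap. They take genes and regions as independent, yet the groups lay on the slides in the same order in each region. Arrays of the regions may also come from the same mice, which the labels do not state. Of the cortex genes, 380 of 386 higher and 933 of 1002 lower ones had the same sign in the hippocampus. Over all 36357 genes the AD changes of the regions had a Pearson correlation of 0.06 and a Spearman correlation of -0.08 across genes, which are not independent replicates. Among 16953 genes well above background on all arrays these were 0.475 and 0.424. No gene differed between regions by limma (4812 at an unadjusted p under 0.05, smallest adjusted p = 0.375), nor without all arrays in doubt (10531), while 3315 did with slide as a fixed block (1532 higher, 1783 lower in the hippocampus).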

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

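The tests weighed here were chosen after the result was seen, except that of choroid plexus tissue, written earlier. In 248 groups of 5 to 7 arrays, 35 highest or lowest arrays stood apart from the rest of their group by a gap test, where chance gives about 1 in 20 groups, 12.4 in all. The value of the nearest other array of the group is given after each.

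Microglia genes stood apart on arrays that went against their labels. The labels do not tie an array of the cortex to one of the hippocampus. The mouse labelled WT_NR replicate 6 had a score of plaque-associated microglia of 0.86 in the cortex (nearest other -0.86) and 0.70 in the hippocampus (-0.55). Its Cst7 was 2.17 (-2.56) and 1.53 (-2.81), and its Itgax 0.34 (-4.32) and -0.43 (-3.53). In the cortex its complement score was 0.47 (-0.35), its score of reactive astrocytes 0.57 (-0.26) and its score of immediate early genes -0.18 (0.24). The hippocampus array AD_NR 2 went the other way, with Cst7 at -2.98 (0.96), Itgax at -3.83 (-1.03) and a score of homeostatic microglia of -0.28 (0.18). It also stood apart in the scores of thalamus, 1.57 (0.10), and synapse, -0.80 (-0.16).

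For the mouse labelled WT_NR replicate 6, transgenes in a mouse labelled WT may explain the pattern: 98.0% of the 393 genes higher in AD lay nearer their AD mean on its cortex array, against 13.2 to 22.9% on WT_NR 3, 4 and 5. NR is argued against, as the highest Cst7 of the other WT_NR cortex arrays was -2.56. A swap with an AD or AD_NR mouse is argued against too, as 0 of their 24 arrays had Prnp at or below the highest WT array. A single wrong label or a swap with a mouse outside the series stays open. For hippocampus AD_NR 2, a sample without transgenes is argued against by its Prnp of 6.51, and NR by Cst7, at least 0.96 on the other AD_NR arrays. Tissue from outside the hippocampus is a candidate explanation, as its hippocampus region score was -2.24 against -0.55 to 0.48 elsewhere, with the thalamus genes Tcf7l2 at 3.41 and Tnnt1 at 2.02.

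Choroid plexus genes stood apart on single arrays: their score was 2.56 on cortex AD 6 (0.23) and -2.94 on hippocampus AD 5 (0.07), where Ttr, the transthyretin gene of that tissue, was 2.49 (5.69). In the hippocampus the list lay lower with NR in both genotypes. Unequal amounts of the tissue in the samples could produce this, as the 17 members rose and fell together within groups (median pair correlation 0.964, highest of the other lists 0.929, median of the others 0.305). A difference between slides and an NR effect cannot be told apart from it. Within slide 6 the median of AD_NR minus AD was -0.68, and -0.19 without AD_NR 2, but the scores spread widely (SD 2.66 and 2.17, n = 5 and 3, AD_NR 2 included) and the exact permutation p was 0.857.

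Unnamed genes made up 922 of the 1020 genes lower in AD cortex. Scaling of dim spots between arrays is a candidate explanation for part of them, as 17.2% were lower again with quantile normalisation. Their median went from -0.92 to -0.71, with a median SE of 0.23 before and 0.24 after, and all 922 stayed below 0. The changes became smaller, and the adjusted p also depends on how many other genes pass. Which of these ended the calls was not tested. Their median level was -3.45, against -2.84 for all genes. A slide difference cannot be told apart, since WT and AD arrays shared no slide; on slide 2, AD minus WT_NR had a median of -0.29. No biological explanation was tested.

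Further arrays stood apart in single values. Hippocampus WT_NR 1 had a spread of repeated spots of 27.1% (nearest other 6.79%), a 75th percentile of 1369 intensity units (2508), 329 spots set aside by the software (126) and App at 6.75 (5.64). Hippocampus AD 1 had a negative-control standard deviation of 35.5 (11.5), 46.9% of spots well above background (74.7%), a 75th percentile of 4036 (2951), a score of homeostatic microglia of -0.21 (0.13) and Sting1 at -0.98 (-0.47). Cortex WT 1 had scores of -0.35 for immediate early genes (0.38), 0.38 for the hippocampus region (-0.12) and -0.65 for the cortex region (0.31), and Per1 at 3.13 (3.73). Cortex AD 4 had an immediate early score of 0.43 (-0.16) and cortex AD 7 a thalamus score of 0.0559 (-0.04). Cortex AD_NR 2 had the lowest cytokine score of its group, 0.29 (0.43), and cortex AD_NR 1 an NAD score of 0.23 (0.07). Hippocampus WT 1 had Itgax at -5.13 (-4.14).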

How the results depend on the processing

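The settings that leave out arrays in doubt were tests chosen after the data were seen, as were the values within slides. Where a value moved, the cause was not tested unless stated. The rise of Cst7 and Prnp in AD kept its direction in both regions under each alternative.

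Scaling moved counts more than directions. For AD against WT in the cortex, 1413 genes became 373 with normexp and quantile, 605 with quantile alone, 466 with z-scores per array and 599 in the authors' table. In the hippocampus 22 became 38, 48, 37 and 47. With normexp 2 genes passed for NR in WT cortex. With quantile normalisation the list tests gave 2 for NR in AD cortex and 4 for the cortex interaction, and in the hippocampus 4 for NR in AD, 0 for NR in WT and 5 for the interaction.

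Slide as a fixed block gave 14744 genes for AD against WT in the cortex, 17912 for NR in WT and 8342 for the interaction, and 0 for AD against WT in the hippocampus by limma (3498 at an unadjusted p under 0.05). In the hippocampus this fit rests on WT_NR arrays to link slides 4 and 5, the noisy WT_NR 1 and the mouse labelled WT_NR replicate 6 among them. In the cortex it rests on the noisy WT_NR 1 and 2, which by construction link slides 1 and 2. Serpina3n turned to -0.28, Nr4a1 to 0.0195 and Il1b to 2.05, and 3315 genes differed between regions. List tests then gave 8, 14 and 1 in the cortex for AD against WT (0 higher and 8 lower, against 16 higher and 1 lower), NR in AD and the interaction, and 9, 4 and 5 in the hippocampus for AD against WT, NR in WT and the interaction. The lists reversed were cortex, AD vs WT: list astrocytes (adjusted p = 0.00403), cortex, AD vs WT: list mitophagy and autophagy (adjusted p = 0.0123), and cortex, NR vs untreated in AD: list meninges and fibroblasts (adjusted p = 0.0473). Slide as a random block gave 7150, 14021 and 5378 cortex genes for AD against WT, NR in WT and the interaction, 140 hippocampus genes for AD against WT, and Il1b at 1.38. Slide with array column gave 13373, 16023 and 7934, 0 in the hippocampus by limma (3966 at an unadjusted p under 0.05), Serpina3n at -0.12, cortex, AD vs WT: Lamp2 at -0.0747 and Il1b at 2.03. Without the noisy arrays slides 1 and 2 share no group, so this block could not be fitted for AD against WT in the cortex.

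Array weights gave 14175 cortex genes for AD against WT, 3990 for NR in WT and 2424 for the interaction, and in the hippocampus 13425 for AD against WT, 6500 for NR in AD, 12929 for NR in WT and 7057 for the interaction. A filter on all arrays gave 75 hippocampus genes for AD against WT and 38 for NR in AD. With it the correlation of the regions was 0.475, and 50 genes were higher in both. A sex-linked covariate gave 9 hippocampus genes for AD against WT. The replicate block joined arrays of different groups within a region that carry the same replicate number. The labels do not state that such arrays belong together. With it 7 hippocampus genes passed for AD against WT and 4 lists for NR in AD.

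Without the noisy arrays the cortex gave 3396 genes for AD against WT, 1 for NR in WT, and 16 and 14 lists for NR in WT and the interaction; the hippocampus gave 1 gene for NR in WT. Without hippocampus AD 1 as well, 157 genes passed for AD against WT and 1 for NR in AD. Without the arrays against their labels the hippocampus gave 103 genes for AD against WT and 12 lists for NR in WT. Without all arrays in doubt the cortex gave 3418 genes for AD against WT, 3 for NR in WT and 167 for the interaction, and 12 and 13 lists for NR in WT and the interaction. The hippocampus gave 305 genes for AD against WT, 1 for NR in WT, 11 lists for NR in AD and 12 for NR in WT. In each cortex fit without WT_NR 1 and 2, the WT_NR arrays left lay on slide 2 and all WT arrays on slide 1. Counts there for NR in WT and the interaction thus carry any slide difference. Within slide 1, whose WT_NR arrays are the noisy ones, 18527 genes passed for NR in WT.

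List calls depended on the correlation between genes and on the slide block. With an estimated correlation camera called 9 lists for AD against WT in the cortex and 0 in each of the other 7 comparisons. Without the noisy arrays these were 2 and 0, without the arrays against their labels 9 and, for AD against WT in the hippocampus, 2, and without all arrays in doubt 10 and 4, with 0 in the NR comparisons and interactions. Without the noisy hippocampus arrays and AD 1 all 4 hippocampus counts were 0. fry called 9, 0, 3 and 0 cortex lists for AD against WT, NR in AD, NR in WT and the interaction, and 5, 1, 0 and 0 hippocampus lists. With mixed directions fry called 0, 2 and 0 cortex lists for the last 3, and 5, 2, 0 and 0 in the hippocampus.

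Leaving out each array in turn gave 464 to 2357 cortex genes for AD against WT, lowest without WT 3 and highest without AD 1, 0 for NR in AD, 0 to 1 for NR in WT and 0 for the interaction. In the hippocampus it gave 8 to 2495 for AD against WT, highest without WT 6, 0 to 380 for NR in AD, highest without AD_NR 1, 0 to 5004 for NR in WT, highest without WT 6, and 0 for the interaction. For AD against WT, each gene of the rule in the methods that had passed was called again without each of the 24 arrays. In the cortex 1143 of these repeated calls stayed past the threshold and 153 did not, and in the hippocampus 251 did and 85 did not. Signal over background limits the dim genes: 46.9% of spots of hippocampus AD 1 were well above background.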

Other observations

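The tests of other splits in this part were written earlier, and the look at clock and proliferation genes was chosen after the values were seen. In AD cortex 2 of 17 clock genes passed. Per1, a light-responsive clock gene, fell by 0.70 ± 0.11 (adjusted p = 0.000825) and by 0.74 with slide as a fixed block, and Nfil3, a clock output repressor, fell by 0.51 ± 0.13 (adjusted p = 0.0331). In the cortex genes of the clock list in phase with Per1 had a median of -0.16 and those against it -0.14, near the all-gene median of -0.14. In the hippocampus they had -0.15 and -0.12, against 0.07 over all genes. In the cortex the clock list did not pass camera (median -0.17, adjusted p = 0.0813). It did with quantile normalisation (cortex, AD vs WT: list circadian clock, adjusted p = 0.000721) and with slide as a fixed block (adjusted p = 0.00158). Its cortex score was 0.22 lower in AD (exact permutation p = 0.0105). Single genes of dividing cells rose in AD cortex, Mki67 by 0.995 ± 0.215 (adjusted p = 0.0137), Top2a by 1.15 ± 0.31 (adjusted p = 0.0389) and Ccnb1 by 0.91 ± 0.25 (adjusted p = 0.0391). Nes, a filament gene of progenitors, fell by 0.57 ± 0.15 (adjusted p = 0.0380). The list of neurogenesis and proliferation did not pass as a whole, with 12 of 16 genes short of the threshold, a median of -0.02 (camera adjusted p = 0.0813) and a score difference of 0.04 (exact permutation p = 0.756).

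The arrays of each comparison were also divided in 100 ways into groups of the same sizes, the real one included. For AD against WT in the cortex, where Cst7, Itgax and the chemokines rose, a chance division is argued against. Only the real one, 1 of 100, gave as many genes, with 1413 against 1203 in the highest other. As untreated WT and AD arrays shared no slide, these divisions cannot tell genotype from slide in either region. In the hippocampus 4 of 100 gave as many, without adjustment over the comparisons, so chance is less clearly argued against. Another division there gave 13261 genes against 22, which points to a structure of the samples. What made it, noisy or outlying arrays among the possibilities, was not tested. For NR in AD, NR in WT and the interaction, with 0 genes each by limma, all 100 gave as many, an outcome that a count of 0 fixes and that tells nothing about chance. The highest others were 1121, 3959 and 1 in the cortex and 3719, 12357 and 7461 in the hippocampus, the large ones pointing to such a structure again. For the difference between regions the real count was 0 as well, which all 100 reach, with 2 in the highest other.

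For the number of gene lists called by camera with its preset correlation, chance cannot be excluded in any comparison. In the cortex 31, 71, 92 and 75 of 100 divisions called as many lists for AD against WT, NR in AD, NR in WT and the interaction, with 17, 8, 7 and 7 in the real ones and 25, 17, 23 and 21 in the highest others. In the hippocampus these were 18, 86, 66 and 49, with 15, 7, 7 and 10 in the real ones and 22, 18, 19 and 19 in the highest others.

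Sex-linked genes gave the same sign on 23 of 24 same-numbered arrays of both regions, and WT 3 differed. Arrays with Xist above the Y-linked mean numbered 3 in WT, 3 in WT_NR, 4 in AD and 3 in AD_NR cortex.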
